A study of Homo sapiens with 66 samples.

How the data were processed

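The material was HCT116, an established human colorectal carcinoma cell line, grown in serum-containing medium or starved for 6 hours in Earle's Balanced Salt Solution, per the labels' protocols. That solution holds salts and glucose and no amino acids or serum. Poly(A) RNA was sequenced from 22 libraries. Chromatin fixed with formaldehyde and sheared by sonication was sequenced from 44 ChIP-seq libraries, of which 27 were immunoprecipitated with antibodies to TDRD3, RNA polymerase II (RNAPII) or RNAPII phosphorylated on serine in its repeat domain (RNAPII-Ser2P), and 17 were input chromatin. The 66 libraries fell into 29 groups of one library kind, genotype and treatment, with at most 3 libraries in a group.

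The values analysed here were raw read counts deposited by the authors, 1 total per sequencing file, with no normalization, per the file headers. The table held 132 rows, 2 for each of the 66 libraries, and the first-mate and second-mate totals were equal in 66 libraries. Each total was therefore taken as a number of read pairs. The row names are sequencing files, so the totals precede mapping. Whether adapter trimming or quality filtering came before the count is not given in the sources used here. The submitters' processing notes name the genome build hg38 and the tools HISAT2, HTSeq, DESeq2, Bowtie2, deepTools, MACS2, bedtools and HOMER, without versions. Counts per gene, peaks and coverage tracks were not used here, so mapped reads, mapped shares and named genes, for which tests had been planned, were not analysed. A model across genes had nothing to act on, and each library contributed 1 value. The table held 0 columns from samples outside the series.

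Each row was matched to its library by set number, assay, genotype, treatment, antibody and replicate number. The titles carry a set number, which the labels do not define. It was treated as a possible batch. Wild-type RNA-seq in set90 reuses replicate numbers of set88 and set89, so set90 formed groups of its own, as did the inputs of set101. In 7 of the 8 ChIP-seq conditions of set88 and set89, the totals of replicates 1 and 2 were identical to the read. Each such pair was counted as 1 sample, which left 59 independent totals. Counting them once was decided after the totals were seen. The design fixed before the data were examined had listed them as separate samples, and that version was run as an alternative. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

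Differences were computed on log2 read pairs. Each comparison used the mean difference within strata, weighted by stratum size, and a two-sided permutation test that exchanged labels within strata. RNA-seq against ChIP-seq had no strata, and its labels were exchanged over all libraries. Strata were library kind with genotype for the treatment, and library kind with treatment for genotypes. Immunoprecipitated and input libraries were compared within experiment, genotype and treatment, and the RNAPII antibodies within genotype and treatment. Up to 20000000 arrangements were enumerated (an exact permutation test). Larger sets used 100000 seeded resamples. Standard errors came from the spread within each side of each stratum. For immunoprecipitated against input a side could pool antibodies and sets. For RNA-seq against ChIP-seq it held all libraries of the assay. The 9 comparisons formed one family for Benjamini-Hochberg adjustment, with a threshold of 0.05. Whether depth followed the replicate number was tested in 4 library kinds, a second family, by exact permutation of the numbers within groups. This second family was chosen after the values were seen. As no gene values were used, libraries were named by the rule set before the data were examined. It takes the lowest and highest read number of each library kind, and every library more than 2-fold from its group mean.

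The stratified test was tested on simulated totals with the real strata and the same spread of 0.82 on the log2 scale for every library, in 200 simulations per setting. The spread of the real libraries differed between groups, which the simulations left out. With independent totals, at an unadjusted threshold of 0.05, a simulated 2-fold depth difference was called in 97.5% of simulations of the treatment comparison, 94% of the TOP3B-KO comparison and 49.5% of the TDRD3-KO comparison. A 1.5-fold difference was called in 64%, 49% and 20%, and with no difference in 6%, 2% and 3.5%. Independent totals leave out the deviation that libraries of one kind, set and replicate number share. With 79.1% of the variance shared in that way, the chance-corrected mean share of the 4 library kinds tested, a 2-fold difference was called in 100%, 99% and 75.5%, a 1.5-fold difference in 84%, 68% and 28%, and no difference in 0%, 0.5% and 0.5%, so the test without a block is then conservative. With a replicate block, the shares under the same variance were 100%, 100% and 82.5% for 2-fold, 99.5%, 99.5% and 44% for 1.5-fold, and 6%, 4.5% and 5% for no difference. Counting precision per library was computed for a transcript or region that receives 1 read pair per 1000000, as a Poisson relative standard deviation. The limit that a count of 0 allows was taken as 3 read pairs of the total. Both cover counting error only. Sequenced pairs without molecular identifiers are not independent molecules, and both are optimistic because unmapped pairs are in the totals. Alternatives were linear read numbers, ranks, leaving out each replicate number, set or library, a replicate block, subsets of library kinds, and medians. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.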

Results

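The series asks how TOP3B, a topoisomerase that acts on both DNA and RNA, and its partner TDRD3, a Tudor-domain protein, affect the transcription response to starvation in HCT116 cells. Wild-type cells were set beside TOP3B-KO and TDRD3-KO knockout cells and TOP3B-Y336F-KI cells, a knock-in that replaces the catalytic tyrosine of TOP3B. The processed data analysed here held 1 measurement per library, its number of sequenced read pairs. They give the depth behind each comparison of the design and no level of any gene or region. Depth is given in M, units of 1000000 read pairs. The 66 libraries were listed with 1311 M in all, or 1242 M with the 7 totals repeated in set88 and set89 counted once. The listed sum comprised 357.8 M in RNA-seq, 707.01 M in immunoprecipitated and 246.5 M in input libraries.

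RNA-seq of wild-type and TOP3B-KO cells, untreated and starved, came from set88 and set89 with 3 libraries per group. Wild-type cells had 13.1 ± 9.16 M read pairs untreated and 17.4 ± 8.18 M starved (SD, n = 3 each). TOP3B-KO cells had 17.6 ± 13.1 M untreated and 12.4 ± 7.06 M starved (SD, n = 3 each). The lowest library of this kind was untreated TOP3B-KO replicate 1, with 2.74 M pairs, and the highest was untreated TOP3B-KO replicate 3, with 27.01 M. All 4 replicate 1 libraries, which belong to set88, lay more than 2-fold below their group means. Untreated wild type was 4.64-fold below with 2.83 M, untreated TOP3B-KO 6.45-fold below, starved TOP3B-KO 2.86-fold below with 4.34 M, and starved wild type 2.06-fold below with 8.49 M. The 8 libraries of set89 ranged from 15.5 to 27.01 M.

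A second RNA-seq experiment, set90, held starved wild-type, TDRD3-KO and TOP3B-Y336F-KI cells with 3 libraries each and 1 untreated wild-type library. Starved wild-type cells had 18.5 ± 6.93 M read pairs, TDRD3-KO cells 14.2 ± 6.28 M and TOP3B-Y336F-KI cells 23.4 ± 8.11 M (SD, n = 3 each). The untreated wild-type library, 7.32 M, was the lowest of this set, and starved TOP3B-Y336F-KI replicate 2, with 30.6 M, was the highest.

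TDRD3 ChIP-seq was listed with 2 replicates per condition, but the total was the same to the read in set88 and set89 for 7 of the 8 conditions. Counted once each, the TDRD3 immunoprecipitates held 11.6 M read pairs in untreated and 10.9 M in starved wild-type cells. In TDRD3-KO cells, which lack the antibody's target, they held 11.1 M untreated and 15.1 M starved. The inputs held 9.13 M in starved wild-type, 5.47 M in untreated TDRD3-KO and 5.97 M in starved TDRD3-KO cells. Untreated wild-type input was the condition whose totals differed, with 3.35 M in set88, the lowest ChIP-seq library and 2.28-fold below its group mean, and 11.9 M in set89. The totals thus gave no measure of replicate spread for the 4 TDRD3 immunoprecipitation conditions.

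RNAPII libraries held 31.02 ± 15.7 M read pairs in untreated wild-type, 25.1 ± 4.63 M in starved wild-type and 23.4 ± 5.83 M in starved TOP3B-KO cells (SD, n = 3 each). Untreated TOP3B-KO cells had 1 RNAPII library, of 73.4 M pairs, the deepest of the 66, while starved TOP3B-KO replicate 3 was the lowest of this kind with 17.6 M. RNAPII-Ser2P libraries held 33.1 ± 5.76 M in untreated wild-type, 32.4 ± 4.33 M in starved wild-type and 33.6 ± 7.74 M in starved TOP3B-KO cells (SD, n = 3 each). Among them, starved TOP3B-KO replicate 1 was the lowest with 24.6 M and starved TOP3B-KO replicate 3 the highest with 38.4 M. The 7 inputs of set91 and set104 ranged from 12.7 M, untreated wild-type replicate 3, to 22.6 M, starved TOP3B-KO replicate 1. The 2 inputs of set101 held 35.4 M in untreated wild-type and 28.3 M in starved TOP3B-KO cells.

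**Figure D1:**
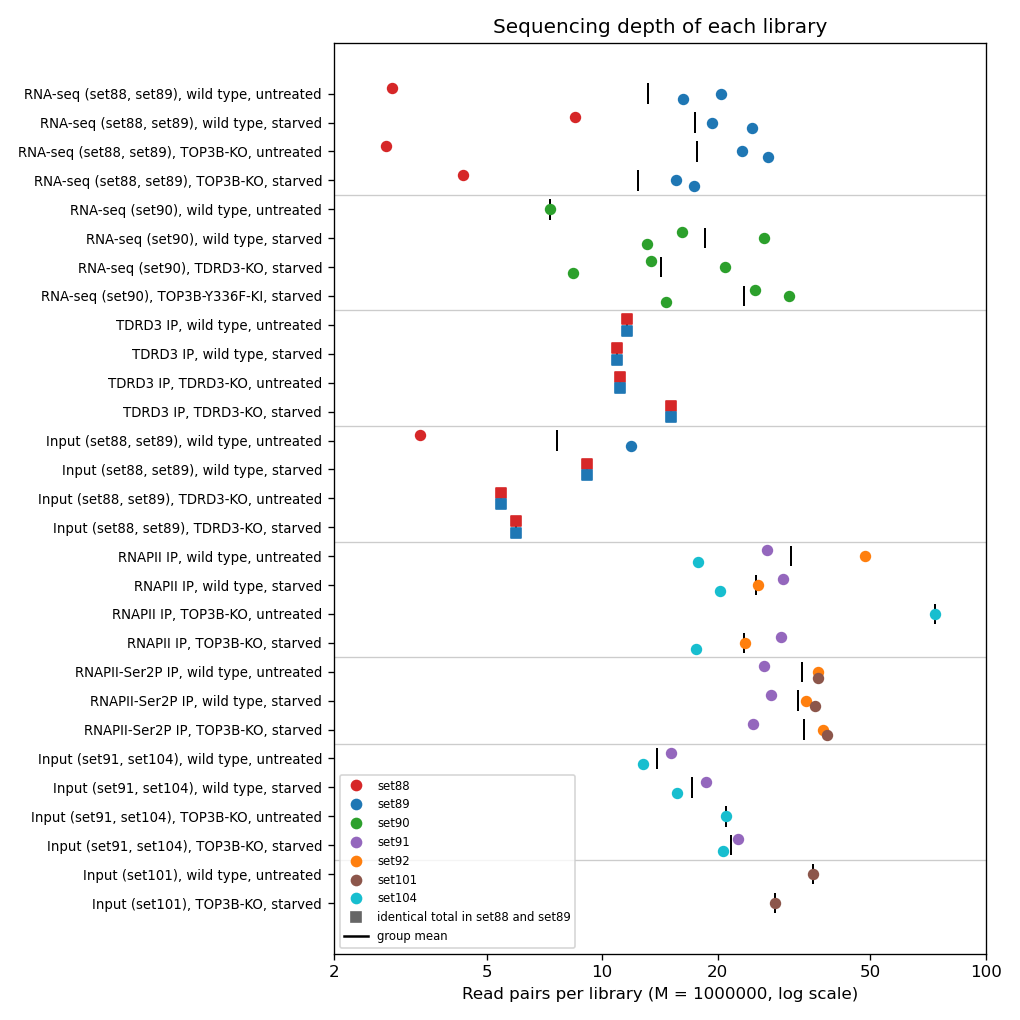
Read pairs per library in M (1000000 pairs, log axis) for each group, with 1 point per library coloured by set number, squares for totals identical in set88 and set89, and a vertical bar at the group mean. The RNA-seq libraries of set88 lie between 2.74 and 8.49 M, below those of set89 (15.5 to 27.01 M), and the deepest library is untreated TOP3B-KO RNAPII with 73.4 M.

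The depth sets what each library can show. A transcript that receives 1 read pair per 1000000 would be represented by 2.74 pairs in the shallowest RNA-seq library, a counting standard deviation of 60.4% of its value, and by 30.6 pairs in the deepest, 18.1%. A count of 0 in those libraries allows up to 1.096 and 0.098 read pairs per 1000000. For the 4 RNA-seq libraries of set88 this counting standard deviation was 34.3% to 60.4%. The corresponding counting standard deviation was 54.6% in the shallowest ChIP-seq library, untreated wild-type input of set88, and 11.7% in the deepest.

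Depth within groups followed the set or replicate number in 3 of the 4 library kinds tested. In set88 and set89 RNA-seq, the replicate number carried 90.6% of the within-group variation in log2 read pairs (exact permutation p = 0.0185, adjusted p = 0.037), and replicate 1 was the lowest in 4 of 4 groups. In set90 it carried 95.3% (exact permutation p = 0.0278, adjusted p = 0.037), with replicate 2 the highest and replicate 3 the lowest in 3 of 3 genotypes. In RNAPII-Ser2P ChIP-seq it carried 94.01% (exact permutation p = 0.0278, adjusted p = 0.037), and replicate 1, of set91, was the lowest in 3 of 3 groups. In RNAPII ChIP-seq it carried 63.3% (exact permutation p = 0.194, adjusted p = 0.194), with replicate 3, of set104, the lowest in 3 of 3 groups. The test took only groups of 3 libraries. It left out the untreated TOP3B-KO RNAPII library, also replicate 3 of set104, with 73.4 M pairs. With 3 groups, 0.0278 is the smallest p that this test can give. By chance the replicate number would carry 33.3% of the variation on average with 3 groups and 25% with 4. These tests were chosen after the values were seen.

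Immunoprecipitated libraries were deeper than inputs of the same experiment (set88 and set89, or the RNAPII sets), genotype and treatment. The difference was 0.70 ± 0.18 on the log2 scale (SE), or 1.62-fold, over 23 immunoprecipitated and 14 input libraries (exact permutation p = 0.0013, adjusted p = 0.0116). Set92 and starved wild-type cells of set101 had no input and were set against inputs of other sets. Matched by set and replicate number, the difference was 0.60 over 15 and 12 libraries (exact permutation p = 0.000362, adjusted p = 0.0033). Within sets the ratio was 1.47 in set91, 1.18 in set101 and 1.53 in set104. It was 2.15 in set88 and 1.57 in set89, which share 7 of 8 totals and are not independent of each other. The set104 ratio included the untreated TOP3B-KO RNAPII library of 73.4 M pairs, at 3.50 times its own input. Starved TOP3B-KO RNAPII of that set, with 17.6 M, was shallower than its input of 20.6 M. The wild-type RNAPII libraries there were deeper than their inputs, 17.8 against 12.7 M untreated and 20.3 against 15.6 M starved. The adjusted p rose above 0.05 when replicate 1 (adjusted p = 0.106) or set91, set92 or set104 was left out, with log2 differences from 0.62 to 0.75.

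RNA-seq libraries held fewer read pairs than ChIP-seq libraries, 16.3 ± 8.15 M (SD, n = 22) against 23.9 ± 13.6 M (SD, n = 37). The log2 difference of -0.57 ± 0.26 (SE) did not pass adjustment (permutation p = 0.0286, adjusted p = 0.129). It passed without the untreated wild-type input of set88 (adjusted p = 0.0455, log2 difference -0.64). The test had no strata and took libraries of one set as independent of each other. Only set88 and set89 contained both assays. RNA-seq was at 0.499 times the listed ChIP-seq depth in set88 and at 2.08 times in set89. As 7 of the 8 ChIP-seq totals are the same numbers in both, these ratios differ mainly through the RNA-seq libraries and are not independent within-batch values. The difference was -0.20 without replicate 1 (adjusted p = 0.75), -0.26 without set88 (adjusted p = 0.675) and -0.92 without set89 (adjusted p = 0.0209), and it turned to 0.46 in set88 and set89 alone (adjusted p = 0.714).

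RNAPII and RNAPII-Ser2P libraries did not differ beyond the replicate spread after adjustment. RNAPII was lower by a log2 difference of -0.37 ± 0.19 (SE, n = 9 each, exact permutation p = 0.0623, adjusted p = 0.187). Leaving out 1 library, untreated wild-type RNAPII replicate 2 with 48.4 M pairs, brought the adjusted p to 0.027 and the log2 difference to -0.49. The difference was -0.61 without replicate 1 (adjusted p = 0.0858), -0.14 without set104 (adjusted p = 0.75) and -0.05 without replicate 3 (adjusted p = 0.906). Within sets, RNAPII was at 1.09 times the RNAPII-Ser2P depth in set91 and at 0.854 times in set92. Replicate 3 of the 2 antibodies came from different sets.

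Starved and untreated libraries, the contrast on which the series rests, did not differ in depth beyond the replicate spread. The log2 difference was 0.09 ± 0.27 (SE) over 26 starved and 22 untreated libraries, 1.07-fold (permutation p = 0.693, adjusted p = 0.78). The log2 difference turned to -0.02 without the untreated wild-type RNA-seq replicate 1 and to -0.01 without the untreated TOP3B-KO RNA-seq replicate 1. It rose to 0.22 without the untreated TOP3B-KO RNAPII library. Starved libraries were deeper in 3 of 7 sets, of which set88 and set89 share ChIP-seq totals, and within sets the ratio ran from 0.701 in set92 to 2.42 in set90. The set90 ratio set 3 starved libraries against 1 untreated library of replicate 3, the lowest replicate number there. Matched on replicate 3 it was 1.79. Of the 22 pairs of libraries that shared kind, genotype, set and replicate number, starved was higher in 12 and lower in 10. A pair was counted once where both its totals were repeated in set88 and set89. The starved wild-type input total of 9.13 M entered the pairs of both sets, at 2.73 times the untreated input in set88 and 0.768 times in set89. The starved library held 3.00 times the pairs of the untreated one in wild-type RNA-seq replicate 1, 2.73 times in the wild-type input of set88 and 0.239 times in TOP3B-KO RNAPII replicate 3, the 3 pairs more than 2-fold apart. The starved minus untreated log2 difference in the RNA-seq of set88 and set89 was 0.70 ± 0.84 in wild-type and -0.18 ± 0.73 in TOP3B-KO cells (SD, n = 3 each). The 1 such wild-type pair of set90, which held no TOP3B-KO, gave 0.84. The genotypes' difference in set88 and set89 of -0.89 ± 0.64 (SE) gave an exact permutation p of 0.3 (adjusted p = 0.675), where 3 against 3 cannot go below 0.1. Depth in these libraries followed the set or replicate number. Taken within replicate numbers, the same contrast between genotypes was -0.92, -0.50 and -1.23 in replicates 1, 2 and 3, negative in 3 of 3. Its SE was then 0.21 (exact permutation p = 0.25, the smallest that 3 pairs allow, adjusted p = 0.563).

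TOP3B-KO libraries differed from wild type by a log2 value of 0.14 ± 0.31 (SE), 1.10-fold, over 16 and 19 libraries (exact permutation p = 0.624, adjusted p = 0.78). Leaving out 1 library moved the value to 0.0028 without untreated wild-type RNA-seq replicate 1, to 0.02 without the untreated TOP3B-KO RNAPII library and to 0.29 without untreated TOP3B-KO RNA-seq replicate 1. Within sets, the ratio of TOP3B-KO to wild type ran from 0.703 in set88 to 1.67 in set104 and was above 1 in 5 of 6 sets. It lay between 1.01 and 1.07 in set89, set91, set92 and set101, and set104 held the untreated TOP3B-KO RNAPII library of 73.4 M pairs. TOP3B-KO was higher in 8 and lower in 8 of the 16 pairs that shared set and replicate number. With a replicate block of set and replicate number, the log2 difference was 0.14 over 16 libraries on each side (exact permutation p = 0.446, adjusted p = 0.643). Single groups, picked after their values were seen, went both ways. TOP3B-KO held more pairs in 3 of 3 inputs, at 1.21, 1.32 and 1.65 times, and 0.968, 1.14 and 1.67 times the wild-type pairs in untreated RNA-seq replicates 1, 2 and 3, a log2 difference of 0.29 ± 1.39 (SE, n = 3 each, exact permutation p = 0.6, not adjusted). This SE ignores the pairing and includes the depth difference between set88 and set89. No SE within replicate numbers was computed for the untreated libraries. Starved RNA-seq held 0.511, 0.804 and 0.709 times the wild-type pairs in replicates 1, 2 and 3, a log2 difference of -0.59 ± 0.79 (SE, n = 3 each, exact permutation p = 0.5, not adjusted). Within replicate numbers the SE was 0.20 (exact permutation p = 0.25, the smallest that 3 pairs allow, not adjusted). Untreated RNAPII, with 1 TOP3B-KO library, held 4.12 times the pairs of the wild-type library of set104.

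TDRD3-KO libraries differed from wild type by -0.24 ± 0.41 on the log2 scale (SE), 0.849 times the depth, over 7 and 8 libraries (exact permutation p = 0.458, adjusted p = 0.75). Leaving out 1 library gave log2 differences from -0.37, without the untreated wild-type input of set88, to -0.10, without TDRD3-KO RNA-seq replicate 3. The ratio was 0.749 in set90, where replicates 1, 2 and 3 gave 0.830, 0.792 and 0.640. It was 1.09 in set88 and 0.794 in set89, which here differ only through the untreated wild-type input (3.35 against 11.9 M), and TDRD3-KO was lower in 6 of 8 pairs that shared set and replicate number. The untreated inputs gave 2 of these pairs from 1 TDRD3-KO total, 1.63 in set88 and 0.459 in set89. For the TDRD3 antibody alone, the knockout held 1.38 times the wild-type pairs when starved and 0.959 times when untreated. With 4 arrangements that comparison could not reach a p below 0.5 (exact permutation p = 1, adjusted p = 1). In set90, TOP3B-Y336F-KI libraries held 1.26 times the wild-type pairs, a log2 difference of 0.34 ± 0.44 (SE, n = 3 each, exact permutation p = 0.5, adjusted p = 0.75). The knock-in was higher in 3 of 3 replicate numbers, at 1.55, 1.16 and 1.12 times, and 3 against 3 cannot go below 0.1. Leaving out 1 library gave log2 differences from 0.11, without TOP3B-Y336F-KI replicate 2, to 0.64, without TOP3B-Y336F-KI replicate 3. Leaving out a replicate number from both genotypes gave 0.19 to 0.43. Within replicate numbers the exact permutation p was 0.25 (adjusted p = 0.54), the smallest p that 3 pairs allow.

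**Figure D2:**
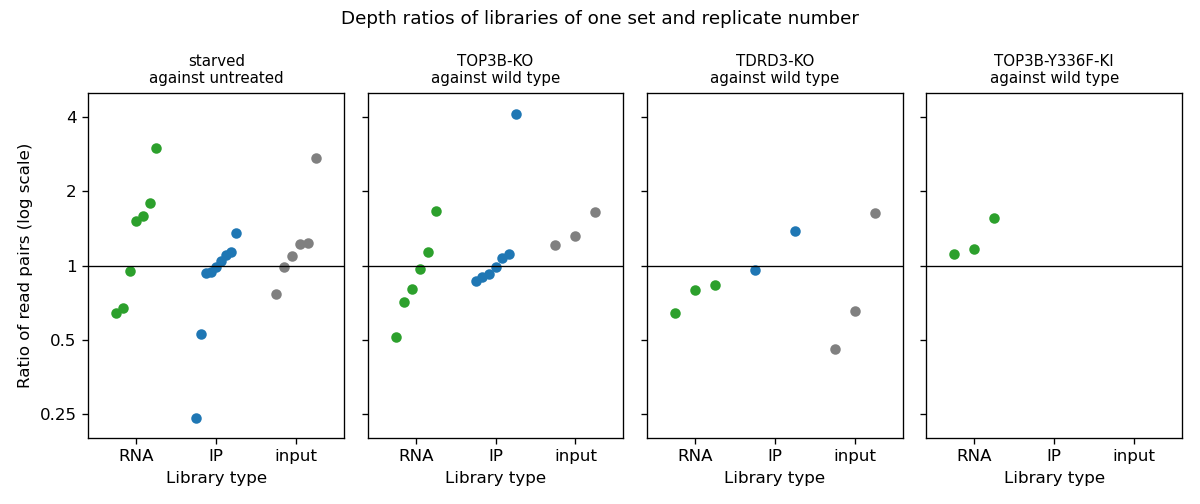
Ratio of read pairs (log axis) between libraries of the same set, replicate number and library kind for each contrast, with pairs of totals repeated in set88 and set89 drawn once, with 1 point per pair placed by library type and a line at a ratio of 1. Starved-to-untreated ratios fall on both sides of the line (12 above, 10 below), and the highest ratio, 4.12, is untreated RNAPII in TOP3B-KO against wild type.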

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

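Counting identical totals once was chosen after seeing the data. Counting them as 2 samples, as first designed, changed no call and gave 0.73 for immunoprecipitated over input (permutation p = 7e-05, adjusted p = 0.00063) and -0.40 for RNA-seq against ChIP-seq (adjusted p = 0.365). The settings with set88 and set89 alone, with their ChIP-seq libraries as one block and with each library left out, and all settings of the treatment by genotype test, were also chosen after seeing the data. The excess of immunoprecipitated over input depth kept its direction in 14 of 14 settings and its call in 10. The log2 difference was 0.75 without set91, 0.65 without set92 and 0.62 without set104, where the adjusted p reached 0.0948, 0.0531 and 0.0601, and from 0.67 to 0.78 when one replicate number was left out. These settings hold fewer samples. RNA-seq against ChIP-seq reached -0.92 without set89 (adjusted p = 0.0209), fell to -0.26 without set88 and turned to 0.46 in set88 and set89 alone. With one replicate number left out it ranged from -0.77 to -0.20, and RNAPII against RNAPII-Ser2P from -0.61 to -0.05. Starved against untreated, never past the threshold, turned to a linear difference of -2.97 M read pairs, to -0.21 on ranks, to -0.059 without set88 and to -0.30 in immunoprecipitated libraries. In starved against untreated over all library kinds, leaving out one replicate number gave log2 differences from -0.11 to 0.23. TOP3B-KO against wild type turned to -0.056 without set104 and -0.15 in RNA-seq alone, and ranged from -0.11 to 0.26 with one replicate number left out. TDRD3-KO against wild type turned to 0.20 in immunoprecipitated libraries. The causes of these turns were not tested. With a replicate block of set and replicate number, log2 differences were 0.60 for immunoprecipitated over input (exact permutation p = 0.000362, adjusted p = 0.0033), 0.04 for starvation and -0.05 for RNAPII against RNAPII-Ser2P. This block has no partner for the untreated wild-type inputs of set88 and set89. With the ChIP-seq libraries of these sets as one block, the values were 0.62 (adjusted p = 0.0119) for immunoprecipitated over input, 0.07 for starvation and -0.24 for TDRD3-KO. Neither block changed a call. With 1 library left out, immunoprecipitated over input ranged from 0.63 to 0.79 and stayed past the threshold, and TDRD3-KO against wild type ranged from -0.37 to -0.10. Group medians differed from means, with 23.2 against 17.6 M in untreated TOP3B-KO RNA-seq and 26.9 against 31.02 M in untreated wild-type RNAPII. A median cannot lie further than the SD from its mean, so the replicate spread could not test this choice. Mapped reads were planned as an alternative and not run.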

Other observations

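All tests in this part were chosen after the values were seen. The ChIP-seq totals of set88 and set89 were identical to the read in 7 of 8 conditions, for inputs and TDRD3 immunoprecipitates alike. Among the other 2138 pairs of libraries 0 had equal totals, which would allow a share of up to 0.14% if the pairs were independent. The pairs share libraries and many join different library kinds, so this limit is only approximate. Equality to the read in 7 of 8 conditions, and in 0 of the other pairs, argues against separate libraries that reached the same depth by chance. The condition that differs, untreated wild-type input, was 3.55-fold shallower in set88, inside the range of 2.28-fold to 9.86-fold by which RNA-seq replicate 1, of set88, was shallower than replicates 2 and 3, of set89. Its set88 entry stands in place 10 of the 12 libraries of that set, after 2 RNA-seq libraries. A candidate explanation is that one set of totals was entered for both sets, and reads of one library deposited under both numbers would give the same totals. The totals alone leave both open, and a comparison of the reads or of coverage between the sets would separate them.

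Depth followed the set or replicate number in 3 of the 4 library kinds tested. Only in set90 did the replicate numbers come from the same set. In set88 and set89 RNA-seq, replicate 1 was set88 and replicates 2 and 3 were set89, with geometric means of 4.11, 19.4 and 20.8 M. In RNAPII-Ser2P ChIP-seq each replicate number came from a different set, so set and number cannot be told apart. The exact permutation p was 0.0278 in set90 RNA-seq, 0.0185 in set88 and set89 RNA-seq and 0.0278 in RNAPII-Ser2P ChIP-seq. This is consistent with same-numbered libraries sharing a preparation or a sequencing pool, a hypothesis that the labels neither state nor exclude. In RNAPII ChIP-seq the exact permutation p of 0.194 leaves it open with 9 libraries, although replicate 3 was the lowest in 3 of 3 groups. The untreated TOP3B-KO RNAPII library, replicate 3 of set104 and outside that test, was the deepest of the 66 with 73.4 M pairs. No biological explanation was tested, since replicate numbers name no biological group.

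No group held 4 or more libraries, and none was tested for a single outlying library. The untreated TOP3B-KO RNAPII library, chosen after its value was seen, held 3.50 times the read pairs of its own input and 4.18 times those of the starved TOP3B-KO RNAPII library of the same set.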
